A study of Caenorhabditis elegans with 9 samples.

How the data were processed

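RNA was measured in 9 libraries from female Caenorhabditis elegans on day 3, with 3 libraries of sorted oocyte P-bodies, 3 of dissected whole oocytes and 3 of extracts of whole animals. Per the labels, the strain carried a fog-2 mutation, GFP on CAR-1 and RFP on PGL-1, and the oocytes were arrested. P-bodies were sorted by what the labels call FAPS, oocytes were dissected, and the whole-animal extracts were neither dissected nor sorted. RNA was taken with a kit made for fixed tissue, with DNase treatment and reversal of the crosslinks of fixed fractions, and removal of debris by centrifugation was left out for the sorted P-bodies alone. The libraries were paired-end and made with a stranded total RNA kit for small inputs, and ribosomal RNA was present in the data. Nothing in the labels says that the replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical.

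The authors deposited a table of raw counts per gene, which its name credits to HTSeq, with 1 column for each library. Reads were aligned with HISAT2 2.1.0 to the WBcel235 build, per the submitters' processing notes. Those notes also name bcl2fastq, FastQC, StringTie, HTSeq and DESeq2, with neither a version nor a role. The counting's strand setting is not given in the sources used. Named genes that overlap another protein-coding gene on either strand are therefore called uncertain. The authors also deposited a StringTie table with TPM values, scaled over the genes of the table, per the file headers. FPKM values and mean coverage per base stand in the same deposited table, and neither entered a test. No column of values was left unmapped to a library.

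Gene identifiers, symbols and coordinates came from the deposited tables and from the Ensembl annotation of WBcel235, release 115. Of 46778 identifiers 46603 were in that annotation, and 31985 of those had identical start and end in both. For 11 genes whose symbols the deposited table held as dates the symbols were restored from the annotation. Histone genes, the repeated ribosomal RNA genes and other families of near-identical copies are uncertain one by one, because reads can be split between the copies.

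Samples were grouped by their labels, and 3 comparisons were made, P-bodies against oocytes, oocytes against whole animals and P-bodies against whole animals. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM factors, robust estimation and all 9 libraries in 1 fit without covariates, which left 6 residual degrees of freedom. Genes passed edgeR's default filter by group (minimum count 10, minimum total 15), which kept 10162 genes, 9622 of them protein coding. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and an adjusted p of a gene below is from this test unless another tool is named. Log2 fold changes are first group over second, with standard errors (SE), and CPM values are scaled by the TMM factors and given as mean ± SD of 3 libraries. TMM sets the typical gene to no change, so a value states the change of a gene relative to the typical gene and not an amount per oocyte or per particle. The same values with library totals alone, without TMM factors, are printed beside the directions.

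For the tests of gene groups, 25 lists were fixed before the data were examined, as were the tests, the alternatives other than those named as added, and the rule for the genes named. They were P-body and mRNA decay proteins, germ granule proteins, germline RNA-binding regulators, reported targets of oocyte translational repressors, maternal embryo patterning and polarity, oocyte eggshell with yolk uptake and egg activation, meiotic chromosome axis with pairing and recombination, cell cycle with spindle and centrosome, the germline small RNA pathway, ribosomal proteins, translation factors, the nuclear-encoded respiratory chain and ATP synthase, mitochondrially encoded mRNAs, the proteasome, glycolysis, heat shock and unfolded protein chaperones, histones, vitellogenins, markers of intestine, of body wall and pharyngeal muscle, of neurons, of hypodermis and cuticle, of gonadal sheath and spermatheca, of coelomocytes and excretory cells, and sperm genes. Some genes stand in more than 1 list. Lists with at least 4 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with the correlation estimated from the data. The list counts in the text are of members called by the gene test over all genes, with the count adjusted over the list alone beside them.

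The rule for named genes took, for each comparison and direction, the 8 genes with the largest log2 change among called protein-coding genes with a class symbol, a mean of at least 50 CPM in the higher group and no overlap between the libraries of both groups, leaving out the msp, his, rpl and rps families. It also took up to 2 members of each list in the direction with more calls and 1 in the other, and 19 preset genes. Of these 18 were tested. The other, fog-2, had 18, 5 and 14 counts in the P-body libraries, 5, 2 and 5 in the oocyte libraries and 4, 6 and 3 in the whole-animal libraries, below the filter. Unless stated otherwise, every library of one group lay above every library of the other for each gene named as risen or fallen, which chance gives for 10% of genes with 3 libraries against 3. Shares of RNA classes were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

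Depth differed between groups. Total counts were 73746300, 78685226 and 70371322 in the P-body libraries, 40195770, 27946955 and 75081411 in the oocyte libraries and 52610950, 44416333 and 68215748 in the whole-animal libraries. Protein-coding genes took 45262531, 54937023 and 47263540 of these counts in P-bodies, 3977759, 3566621 and 7905996 in oocytes and 3999690, 3226465 and 5129627 in whole animals. Reads carried no molecular identifiers in the values used here, and spreads between libraries cover more than counting error. No pair of replicates held identical values or agreed within sampling noise. Over genes, chi-square per degree of freedom was at least 83.3 between P-body libraries, 44.6 between oocyte libraries and 4.19 between whole-animal libraries. Chi-square grows with depth, so these values do not rank the groups by spread. Pearson correlations of log CPM were 0.987 to 0.992 between P-body libraries, 0.907 to 0.943 between oocyte libraries and 0.953 to 0.965 between whole-animal libraries. By this measure the oocyte libraries agreed least. The gene test estimated each gene's spread from all groups together, so it did not treat the oocyte libraries as more variable.

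The tests were checked on simulated counts with known changes, drawn from the mean of each gene over these samples and from their library sizes. In each comparison 67, 67 and 66 genes were changed by factors of 1.5, 2 and 4, and all others had equal means in the groups. The real comparisons called 1344 to 6790 genes and differed in make-up. The rates that follow may therefore not hold for them, and they do not test the scaling. For P-bodies against oocytes (8796 genes) edgeR recovered 18.0% of genes changed 1.5-fold, 48.1% of those changed 2-fold and 74.1% of those changed 4-fold, and 11.2% of its calls were false. For oocytes against whole animals (8636 genes) these were 7.02%, 44.6%, 71.2% and 5.33%. For P-bodies against whole animals (8873 genes) they were 24.6%, 50%, 81.7% and 7%.

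The alternatives were RLE factors, library totals alone, DESeq2 1.42.0, no filter, a stricter filter (at least 10 CPM in at least 3 libraries), the replicate number as a block, a fit of the 6 libraries compared, limma-voom with weights per group, removal of rRNA and mitochondrially encoded genes, thinning to the smallest total, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) with and without a filter of mean TPM of at least 1, a test against a 1.5-fold change, leaving out each library in turn, camera with an estimated correlation and fry. Offsets on transcript length, without and with the replicate block, and thinning of the protein-coding counts to the smallest protein-coding total were added after seeing the data. Offsets on GC content were not run, because no genome sequence was used here. Plots were drawn with matplotlib 3.10.9.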

Results

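The series set the RNA of oocyte P-bodies beside that of the dissected oocytes and of whole animals. P-bodies are cytoplasmic granules of protein and mRNA, marked here by GFP on CAR-1, an RNA-binding protein of these granules. RFP marked PGL-1, a protein of the germ granules. Each group had 3 libraries, with 27946955 to 78685226 counts per library.

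The make-up of the RNA differed most between the sorted P-bodies and the other groups. Ribosomal RNA genes took 33.4% ± 4.23 of all counts in P-bodies, 88.0% ± 1.05 in oocytes and 91.6% ± 0.151 in whole animals (mean ± SD, n = 3 each). Protein-coding genes took 66.1% ± 4.32, 11% ± 1.5 and 7.46% ± 0.176. A single gene of the large ribosomal RNA, rrn-3.1, one of a repeated family and so uncertain as a gene, took 30.9% of P-body, 81.6% of oocyte and 85.7% of whole-animal counts. In each pair of groups every library of one lay above every library of the other for both classes (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows).

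**Figure D1:**
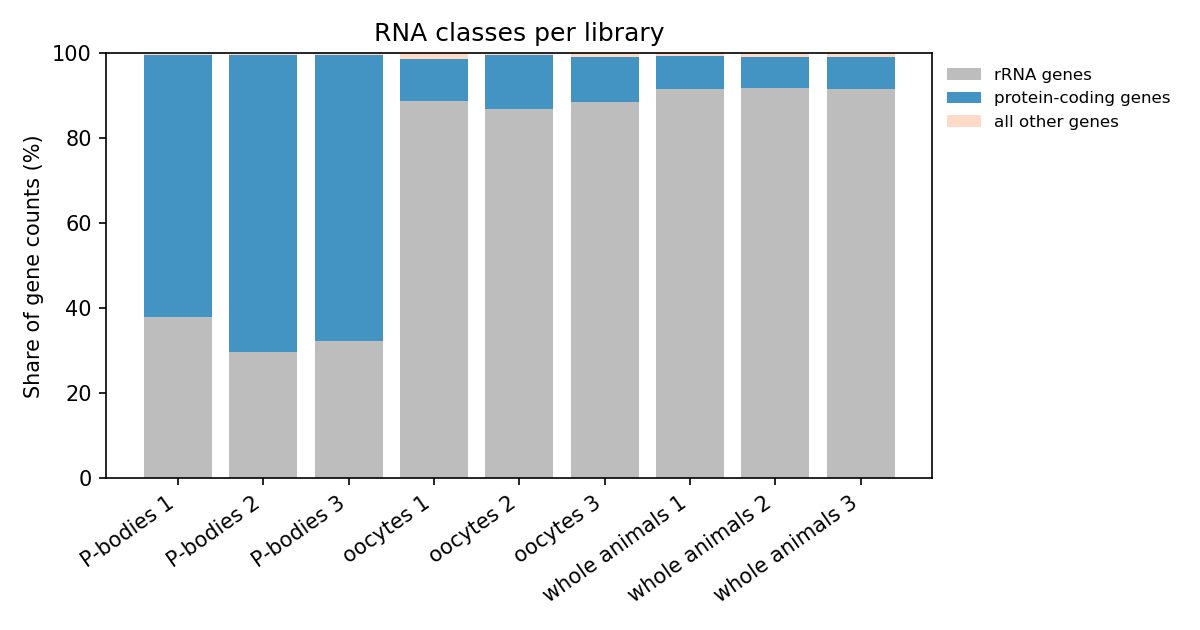
Stacked bars give the share of each library's counts (percent, linear axis from 0) that fell on ribosomal RNA genes, protein-coding genes and all other genes, for 3 libraries each of P-bodies, oocytes and whole animals. Ribosomal RNA averages 33.4% in P-bodies against 88.0% in oocytes and 91.6% in whole animals.

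Within the protein-coding counts, the genes of ribosomal proteins took 0.609% ± 0.0908 in P-bodies, 4.77% ± 0.424 in oocytes and 4.85% ± 0.279 in whole animals. The 12 mRNAs encoded in mitochondria took 0.0106% ± 0.00440, 0.542% ± 0.196 and 0.648% ± 0.108. Vitellogenins, the yolk proteins made in the intestine, took 0.335% ± 0.0993, 0.967% ± 0.531 and 9.25% ± 0.651. Against oocytes, P-bodies had p = 0.1, the floor, in all 3 families (exact permutation tests, n = 3). Among counts without rRNA it was 0.2 for vitellogenins. Oocytes against whole animals gave 0.1 for vitellogenins and 0.6 for the others. As shares of all counts, ribosomal RNA included, the direction differed for some families. Vitellogenins then took 0.220% ± 0.0612 in P-bodies and 0.102% ± 0.0467 in oocytes. Histone genes took 0.384% ± 0.0140 against 0.129% ± 0.0289 of all counts, but 0.583% ± 0.0514 against 1.16% ± 0.194 of protein-coding counts. Ribosomal proteins took 0.402% ± 0.0651 of all counts in P-bodies, 0.525% ± 0.0474 in oocytes and 0.362% ± 0.0276 in whole animals (P-bodies against whole animals, exact permutation p = 0.5).

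Because of this difference in make-up, directions depended on the scaling. TMM factors were 3.64 to 3.81 in P-bodies, 0.576 to 0.719 in oocytes and 0.399 to 0.425 in whole animals. With library totals in their place, the median log2 fold change of all genes moved by 2.51 for P-bodies against oocytes, 0.68 for oocytes against whole animals and 3.19 for P-bodies against whole animals. On log2(TPM + 1) it moved by 2.19, 0.56 and 2.78. The list medians on TPM had the sign of those with library totals for every list in all 3 comparisons. Rises and falls below are relative to the typical gene (TMM) and stand beside the value with library totals.

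P-bodies against oocytes addressed which transcripts the granules held more or less of than the cell they came from. Messages for germline RNA-binding regulators and for targets of translational repression in oocytes were higher in P-bodies, and messages for ribosomal proteins, mitochondrial proteins and the proteasome were lower relative to the typical gene. With an estimated correlation between genes the lists of ribosomal proteins (camera adjusted p = 0.0366) and the proteasome (0.0371) passed, but not germline RNA-binding regulators and repressor targets (adjusted p = 0.0657 each), the nuclear-encoded respiratory chain (0.122) or mitochondrially encoded mRNAs (0.149). With library totals only the lists of ribosomal proteins and mitochondrially encoded mRNAs kept a median below 0. The message of spn-4, a regulator of maternal mRNA in the early embryo (WBGene00004984, V 6783187 to 6784922), rose by a log2 value of 1.85 ± 0.11 (SE) from 251 ± 5.41 to 906 ± 55.1 CPM (adjusted p = 4.31e-08). That of pos-1, which encodes a zinc finger protein of germline fate (WBGene00004078, V 8414085 to 8415254), rose by 1.53 ± 0.10 from 156 ± 13 to 451 ± 7.18 CPM (adjusted p = 1.14e-07). The ribosomal protein message rps-13 (WBGene00004482, III 6374048 to 6374997) had a log2 fold change of -3.67 ± 0.13, with 30.6 ± 1.46 CPM in oocytes and 2.41 ± 0.173 in P-bodies (adjusted p = 4.10e-09). With library totals these 3 values were 4.36, 4.05 and -1.16.

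Of 10162 genes, 5640 changed, 2715 higher and 2925 lower in P-bodies. Of these, 1524 were at least 2-fold higher and 1924 at least 2-fold lower, and 278 and 1017 at least 4-fold. With library totals 8093 genes were higher and 340 lower, and 1748 of the calls had the opposite sign. On log2(TPM + 1) the split was 7987 to 270, on log2(TPM + 0.1) 7969 to 286, with a mean TPM of at least 1 it was 6768 to 252 and without a filter 8082 to 277. A stricter filter left 1723 higher and 1653 lower.

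Of 32 germline RNA-binding regulators 24 rose and 1 fell (24 and 2 adjusted over the list alone), with a median log2 change of 0.94, or 3.45 with library totals (camera adjusted p = 1.38e-08, and adjusted p = 0.0657 with an estimated correlation). Beside spn-4 and pos-1, the list held a rise of cpb-3, a homolog of the cytoplasmic polyadenylation element binding proteins (1.59 ± 0.09, adjusted p = 3.24e-08). The message that fell was rnp-8 (-0.54 ± 0.10, adjusted p = 0.000685), which lay at 1.97 with library totals. Of the preset genes in this list, lin-41 rose by 0.99 ± 0.11 (adjusted p = 1.04e-05), oma-2 by 0.77 ± 0.10 (3.51e-05), oma-1 by 0.60 ± 0.09 (0.000148) and mex-3 by 0.52 ± 0.13 (0.00519). The value of puf-5, 0.11 ± 0.11, did not pass (adjusted p = 0.423). It passed without oocyte library 2 (0.28, adjusted p = 0.0413) and without a filter (0.33), and lay at 2.62 with library totals.

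Of 32 reported targets of oocyte translational repressors 23 rose and 4 fell (24 and 4 adjusted over the list alone), with a median of 0.91, or 3.41 with library totals (adjusted p = 2.05e-08, and adjusted p = 0.0657 with an estimated correlation). Among them was zif-1, which encodes a substrate adapter of a ubiquitin ligase (WBGene00006977, III 9002779 to 9004839). It rose by 2.0 ± 0.09, from 28.9 ± 0.291 to 115 ± 4.01 CPM (adjusted p = 7.75e-09). Other members were tra-2, a sex determination gene (1.70 ± 0.10), nos-2, a Nanos homolog (1.45 ± 0.10), and glp-1, a Notch receptor of the germline (1.27 ± 0.10). Values of zif-1, nos-2 and glp-1 are uncertain because a gene on the opposite strand overlaps each. In the other direction cul-4, a cullin, was called (-1.03 ± 0.12, adjusted p = 9.46e-06), at 1.47 with library totals. The yolk receptor rme-2, also in this list, fell by 0.80 ± 0.11 (adjusted p = 4.18e-05), at 1.71 with library totals.

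Of 31 maternal patterning and polarity genes 16 rose and 7 fell (16 and 8 adjusted over the list alone), with a median of 0.52, or 3.02 with library totals (adjusted p = 0.00931, and adjusted p = 0.357 with an estimated correlation). The Notch ligand apx-1 rose by 1.42 ± 0.09, and gpr-2, a regulator of spindle position, fell by 1.85 ± 0.13 (0.67 with library totals). Of 36 meiotic chromosome genes 19 rose and 7 fell (20 and 8 adjusted over the list alone), with a median of 0.40, or 2.91 with library totals (adjusted p = 0.00431, and adjusted p = 0.219 with an estimated correlation). Among them the pairing protein gene zim-1 rose by 1.78 ± 0.10 (uncertain, overlapped on its own strand), syp-6 of the synaptonemal complex rose by 1.58 ± 0.11, and the kinase gene plk-2 fell by 0.83 ± 0.10 (1.69 with library totals). With the stricter filter neither list passed, at adjusted p = 0.0583 and 0.122 (ranges over the alternatives 1.81e-07 to 0.0583 and 2.98e-08 to 0.122).

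The cell cycle, spindle and centrosome list went mostly the other way. Of its 50 members 31 fell and 10 rose (32 and 10 adjusted over the list alone), with a median of -0.42, or 2.08 with library totals (adjusted p = 0.00431, and adjusted p = 0.195 with an estimated correlation). The checkpoint kinase gene bub-1 fell by 2.15 ± 0.11 and mat-2, of the anaphase-promoting complex, by 1.79 ± 0.10 (0.35 and 0.71 with library totals), whereas zen-4, a kinesin of cytokinesis, rose by 1.47 ± 0.10 (uncertain, overlapped on the opposite strand). With library totals the sign of the list's test turned (adjusted p = 0.000551, range over the alternatives 0.000551 to 0.0333), while its median of 2.08 stayed below the 2.51 by which that scaling raised the median gene.

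Messages of the granules' own proteins did not move together. Of 23 genes for P-body and decay proteins 8 rose and 6 fell (8 and 6 adjusted over the list alone), and the list did not pass (median -0.11, mean 0.09 and test upward, 2.39 with library totals, adjusted p = 0.432). The decapping enzyme gene dcap-2 rose by 2.05 ± 0.11 (uncertain, overlapped on the opposite strand) and the deadenylase gene panl-2 by 1.33 ± 0.10, while the poly(A)-binding protein gene pab-1 fell by 1.52 ± 0.12 (0.99 with library totals). The tagged car-1 (WBGene00012484, I 12904470 to 12906212) fell by 0.66 ± 0.16, from 279 ± 60.6 to 176 ± 26.3 CPM (adjusted p = 0.00366), and lay at 1.85 with library totals. Without oocyte library 2 its value was -0.42. For cgh-1, the helicase of these granules, the value was 0.12 ± 0.12 (adjusted p = 0.402). It passed without oocyte library 2 (0.30, adjusted p = 0.0238) and without a filter (0.34), and lay at 2.63 with library totals. Of 22 germ granule genes 10 fell and 3 rose (10 and 3 adjusted over the list alone, median -0.32, or 2.19 with library totals, adjusted p = 0.0854). In this list csr-1, an Argonaute, fell by 2.13 ± 0.09 (0.38 with library totals), pgl-3 fell by 0.72 ± 0.14 (1.79) and meg-1 rose by 0.55 ± 0.09. The tagged pgl-1 (WBGene00003992, IV 6974401 to 6977318) lay at 0.13 ± 0.13 (adjusted p = 0.42). It passed without oocyte library 2 (0.37, adjusted p = 0.0110) and without a filter (0.35), and lay at 2.63 with library totals. Of 36 small RNA pathway genes 17 rose and 12 fell (18 and 12 adjusted over the list alone, median 0.29, or 2.79 with library totals, adjusted p = 0.463).

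Of 80 ribosomal protein genes 79 fell and 1 rose (the same counts adjusted over the list alone). The median was -3.05, and -0.53 with library totals (adjusted p = 5.63e-85, and adjusted p = 0.0366 with an estimated correlation). Beside rps-13, rpl-34 fell by 3.09 ± 0.10 (-0.58 with library totals). The exception, rpl-41.1, lay at 1.59 ± 0.643 CPM in P-bodies and 0.673 ± 0.281 in oocytes (1.21 ± 0.43, adjusted p = 0.0288), and its call was lost without P-body library 1 (0.92, adjusted p = 0.147) or 3 (1.19, adjusted p = 0.0812). Of 37 translation factors 26 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.82, or 1.69 with library totals (adjusted p = 4.66e-07, and adjusted p = 0.0806 with an estimated correlation). The fall was 2.15 ± 0.12 for iff-1 and 1.74 ± 0.12 for eif-3.I (0.36 and 0.78 with library totals), and the scaffold gene ifg-1 rose by 0.76 ± 0.10.

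All 12 mitochondrially encoded mRNAs fell (12 adjusted over the list alone), with a median of -5.53, or -3.0 with library totals (adjusted p = 9.37e-12, and adjusted p = 0.149 with an estimated correlation). The largest fall of any gene named by the rule was that of ctc-3, a subunit of cytochrome c oxidase (WBGene00010962, MtDNA 5678 to 6449). It stood at 263 ± 38 CPM in oocytes and 4.71 ± 1.70 in P-bodies, a log2 fold change of -5.80 ± 0.26 (adjusted p = 2.21e-08, -3.29 with library totals). Of the 8 largest falls among genes with a class symbol and at least 50 CPM in oocytes 7 were mitochondrial, the others being nduo-1, nduo-5, atp-6, ctc-1, ctb-1 and nduo-4, at -5.71 to -5.29. Those of nduo-1, nduo-5 and atp-6 are uncertain because a gene on the same strand overlaps each. The eighth was skpo-1, which encodes a peroxidase (-5.30 ± 0.31, or -2.77 with library totals). On log2(TPM + 1) the call of nduo-4 was lost (-1.86). Of 37 nuclear-encoded respiratory genes 29 fell and 1 rose (30 and 1 adjusted over the list alone), with a median of -0.85, or 1.65 with library totals (adjusted p = 3.06e-07, and adjusted p = 0.122 with an estimated correlation). Among them cyc-2.1, a cytochrome c gene, fell by 2.32 ± 0.13 (0.18 with library totals, uncertain, overlapped on its own strand), and sdhd-1 lay at 0.44 ± 0.17 (adjusted p = 0.0415), a call lost without oocyte library 3 (0.31) and without P-body library 1, 2 or 3 (0.43, 0.43 and 0.48), and with the counts thinned to the smallest total (0.28).

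Of 32 proteasome genes 31 fell (32 adjusted over the list alone), with a median of -0.98, or 1.53 with library totals (adjusted p = 6.55e-11, and adjusted p = 0.0371 with an estimated correlation). The fall was 1.57 ± 0.10 for pbs-7 and 1.45 ± 0.09 for rpn-1 (0.93 and 1.06 with library totals). Of 18 glycolysis genes 13 fell (13 adjusted over the list alone), with a median of -1.07, or 1.45 with library totals (adjusted p = 3.4e-07, and adjusted p = 0.0366 with an estimated correlation). Among them gpd-4 fell by 2.3 ± 0.13 and enol-1 by 2.0 ± 0.11 (0.20 and 0.51 with library totals). Of 16 chaperone genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -1.16, or 1.34 with library totals (adjusted p = 0.000536, and adjusted p = 0.33 with an estimated correlation). The Hsp70 gene hsp-1 fell by 2.61 ± 0.19, from 734 ± 174 to 120 ± 19.3 CPM, and hsp-3 by 3.15 ± 0.15 (-0.10 and -0.64 with library totals), whereas hsf-1, the heat shock transcription factor, rose by 1.64 ± 0.11. With library totals the calls of translation factors, respiratory genes, proteasome, glycolysis and chaperones were lost, at adjusted p = 0.684, 0.718, 0.603, 0.315 and 0.275. Over the other alternatives the lowest values were 2.61e-09, 1.79e-09, 2.04e-14, 3.00e-08 and 1.92e-06.

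Of 49 histone genes, whose copies cannot be told apart with certainty, 30 fell and 5 rose (31 and 5 adjusted over the list alone), with a median of -1.91, or 0.65 with library totals (adjusted p = 6.67e-06, and adjusted p = 0.32 with an estimated correlation). Among them his-63 fell by 2.44 ± 0.17 and his-48 by 1.98 ± 0.14 (0.08 and 0.51 with library totals), and the linker histone gene hil-5 rose by 1.63 ± 0.11. Of 23 eggshell, yolk uptake and egg activation genes 13 fell and 7 rose (14 and 7 adjusted over the list alone, median -0.55, or 1.95 with library totals), and the list did not pass (adjusted p = 0.38). The largest rise in this list was that of the kinase gene mbk-2 (2.15 ± 0.10, from 103 ± 6.77 to 457 ± 18.7 CPM), and perm-4, an eggshell gene, fell by 4.44 ± 0.31 (-1.94 with library totals).

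Lists of muscle, sheath and intestine markers fell relative to the typical gene, with medians above 0 with library totals. Of 29 muscle markers 22 fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -2.46, or 0.09 with library totals (adjusted p = 6.73e-05, and adjusted p = 0.403 with an estimated correlation). The muscle myosin gene myo-3 fell by 4.11 ± 0.29 and the troponin gene mup-2 fell by 4.2 ± 0.33 (-1.58 and -1.68 with library totals), while the integrin gene pat-3 rose by 1.01 ± 0.13. For unc-54, another muscle myosin, the value was -2.40 ± 0.53 (adjusted p = 0.00717, 0.19 with library totals), and -1.52 without oocyte library 1. Of 13 gonadal sheath and spermatheca markers 7 fell (7 adjusted over the list alone), with a median of -2.08, or 0.31 with library totals (adjusted p = 0.000193, and adjusted p = 0.0371 with an estimated correlation). The sheath innexin gene inx-8 fell by 5.45 ± 0.25 and the collagen gene emb-9 by 3.42 ± 0.20 (-2.93 and -0.89 with library totals). Of 33 intestine markers 18 fell (18 adjusted over the list alone), with a median of -1.64, or 0.90 with library totals (adjusted p = 0.0276, and adjusted p = 0.622 with an estimated correlation). That call was lost without oocyte library 1 (adjusted p = 0.0782) and with the stricter filter (0.128, range 9.14e-06 to 0.128). Among its members lbp-6 fell by 3.42 ± 0.33 (uncertain, overlapped on the opposite strand) and ifc-2 by 2.05 ± 0.25 (0.47 with library totals).

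All 6 vitellogenins fell (6 adjusted over the list alone, median -1.39, or 1.18 with library totals), but the list did not pass (adjusted p = 0.19). The value of vit-2 was -1.65 ± 0.37 (adjusted p = 0.00425, 0.92 with library totals), a call lost without a filter (-1.42). That of vit-6 was -1.41 ± 0.41 (adjusted p = 0.0166, 1.15 with library totals), with overlapping libraries and a call lost without oocyte library 3 (-1.35, adjusted p = 0.0695), without a filter (-1.19) and with length offsets (-1.28), which were added after seeing the data. Lists that did not pass were neuron markers (5 of 24 rose, 3 adjusted over the list alone, median 0.29, or 0.02 with members at 0 set to their bound, and 2.81 with library totals, adjusted p = 0.337) and hypodermis and cuticle (3 of 22 rose and 6 fell, likewise adjusted over the list alone, median -1.16, or 1.24 with library totals, adjusted p = 0.818). Coelomocyte and excretory markers had 2 of 9 higher and 2 lower (2 and 1 adjusted over the list alone, median -0.10, mean 0.16 and test upward, or 2.40 with library totals, adjusted p = 0.27). Of 84 sperm genes only 7 were tested and 1 rose, at a median of 0.59, or 0 with bounds and 3.12 with library totals (adjusted p = 0.818). None passed when adjusted over the list alone (edgeR, with 1 at an unadjusted p under 0.05, and 1 by DESeq2).

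The 8 largest rises were ranked among genes with a class symbol and at least 50 CPM in P-bodies. They were those of the kinase genes hpk-1 (2.27 ± 0.13), mbk-1 (2.24 ± 0.12), mom-4 (2.23 ± 0.19) and mbk-2, the GTPase-activating protein gene gap-2 (2.18 ± 0.10, uncertain, overlapped on the opposite strand), hrdl-1 (2.17 ± 0.11), the Numb homolog num-1 (2.17 ± 0.10) and fath-1 (2.16 ± 0.14). Adjusted p was 1.32e-06 for mom-4 and 8.48e-08 or lower for the others, and with library totals all 8 rises stayed rises. Across 9610 protein-coding genes Spearman rho of the fold change was -0.0428 with transcript length and -0.0649 with coding length. With oocyte CPM it was -0.0201 (-0.261 to 0.0123 over library pairs) and with 3' UTR length, over 9016 genes, 0.110 (0.00564 to 0.118). Genes are not independent replicates, so no p is given. The stricter filter (4039 genes) gave -0.217 with oocyte CPM.

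**Figure D2:**
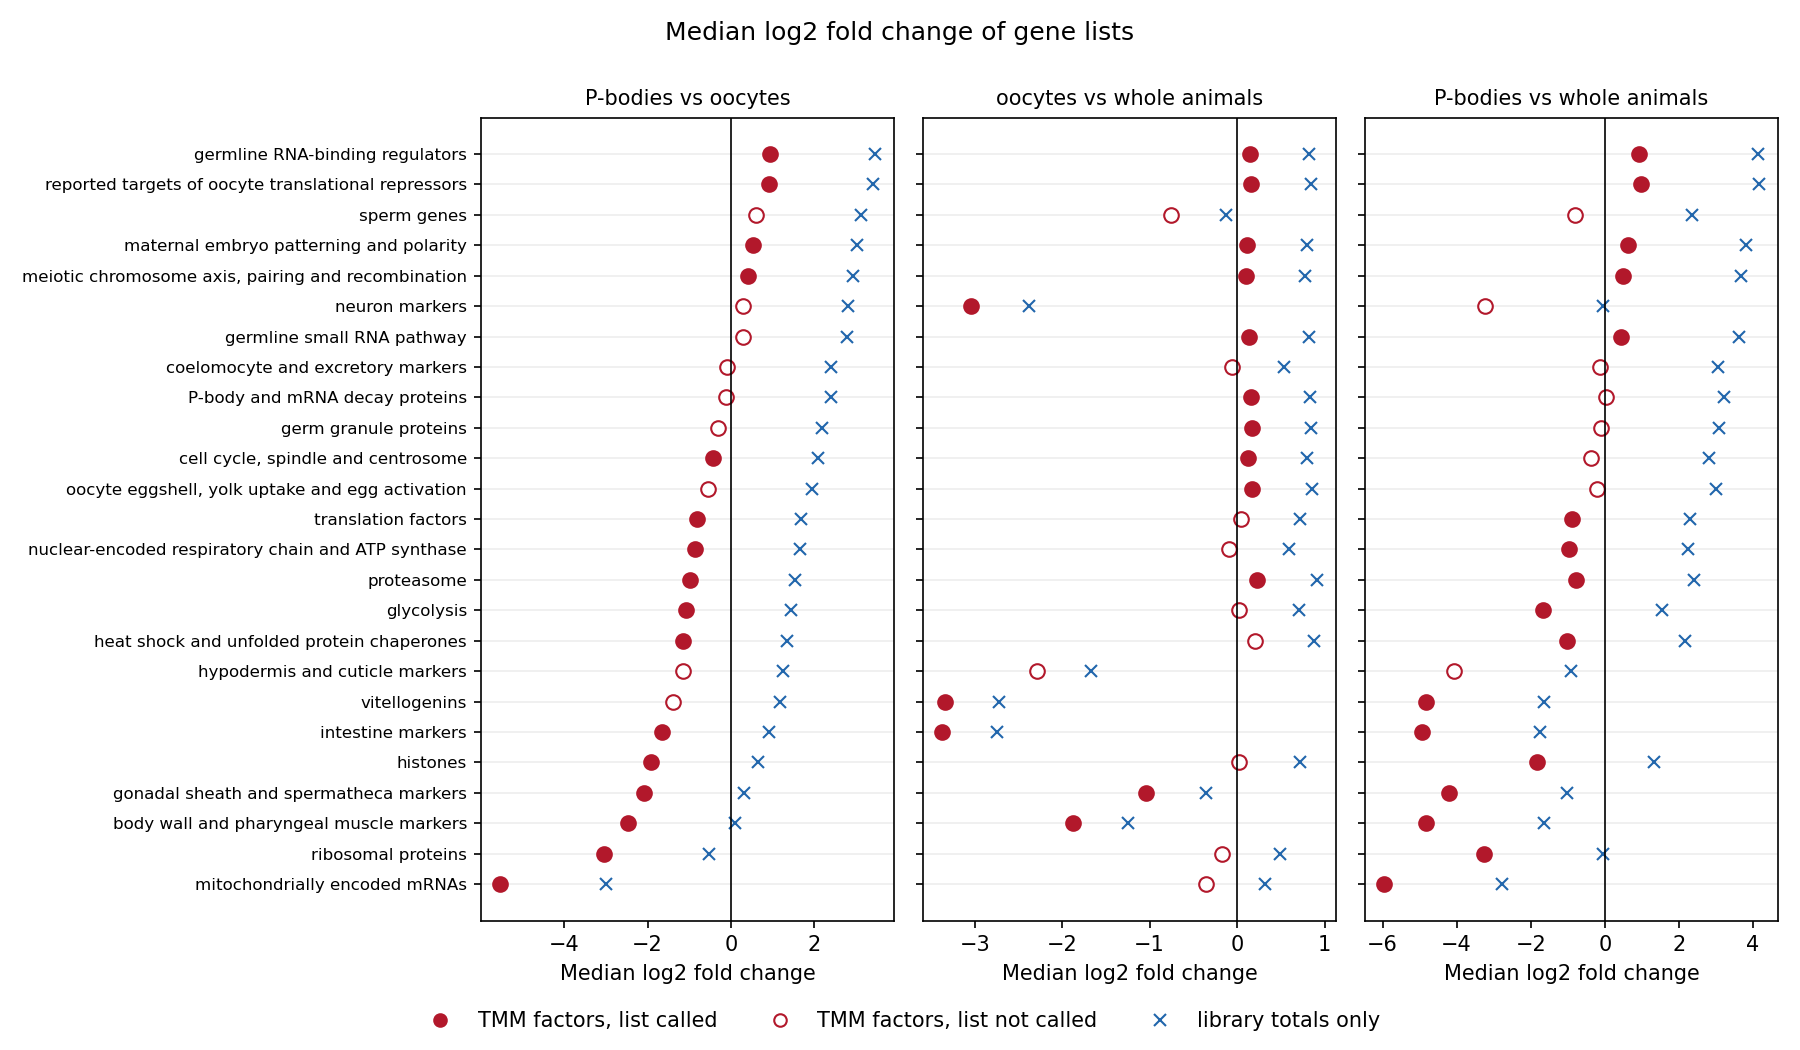
Points give the median log2 fold change of each gene list in 3 panels, P-bodies against oocytes, oocytes against whole animals and P-bodies against whole animals. Circles use TMM factors, filled where camera called the list, and crosses use library totals alone. For P-bodies against oocytes ribosomal proteins (-3.05 and -0.53) and mitochondrially encoded mRNAs (-5.53 and -3.0) keep their sign, while the circles of other lists below 0, such as the proteasome (-0.98 and 1.53), have crosses above 0.

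Oocytes against whole animals asked which transcripts dissection kept or lost. Genes of the intestine, muscle and neurons were lower in the dissected oocytes, and lists of germline genes were slightly higher relative to the other genes. These list calls were made by camera at its preset correlation, and with an estimated correlation 0 of 25 lists passed (lowest adjusted p = 0.0868, 8 at an unadjusted p under 0.05), while camera at the preset correlation called 16 on DESeq2 statistics. The vitellogenin message vit-2 (WBGene00006926, X 5101032 to 5106173) stood at 4729 ± 713 CPM in whole animals and 499 ± 263 in oocytes, a log2 fold change of -3.24 ± 0.40 (adjusted p = 0.000768), and -2.62 with library totals. Germline messages differed little, as in spn-4 (0.25 ± 0.11, adjusted p = 0.157) and pos-1 (0.15 ± 0.10, adjusted p = 0.387).

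Of 10162 genes 1344 changed, 72 higher and 1272 lower in oocytes, and 1190 of the latter were at least 2-fold lower. With library totals 5278 were higher and 1203 lower, and on log2(TPM + 1) 4202 and 1404, on log2(TPM + 0.1) 4315 and 1391, with a mean TPM of at least 1 4298 and 616, and without a filter on TPM 2835 and 1440. DESeq2 called 363 higher and 1528 lower, edgeR without a filter 320 and 1598, and edgeR with the stricter filter 6 and 196. Without oocyte library 1, 2 or 3 the split was 99 to 1436, 58 to 1138 and 227 to 1064, and without whole-animal library 1, 2 or 3 it was 28 to 882, 23 to 865 and 32 to 907.

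All 6 vitellogenins fell (6 adjusted over the list alone), with a median of -3.34, or -2.72 with library totals (adjusted p = 1.65e-11, and adjusted p = 0.119 with an estimated correlation). Beside vit-2, vit-6 fell from 5223 ± 542 to 503 ± 268 CPM and vit-5 from 4966 ± 449 to 425 ± 256 CPM. Of 33 intestine markers 26 fell (30 adjusted over the list alone), with a median of -3.37, or -2.75 with library totals (adjusted p = 5.91e-27, and adjusted p = 0.0868 with an estimated correlation). Among them the intermediate filament gene ifc-2 fell by 3.16 ± 0.24 and the proton pump gene vha-6 by 3.51 ± 0.29. Of 29 muscle markers 19 fell (24 fell and 1 rose adjusted over the list alone), with a median of -1.88, or -1.25 with library totals (adjusted p = 2.34e-14, and adjusted p = 0.138 with an estimated correlation). The pharyngeal myosin gene myo-2 had 9.88 ± 1.38 CPM in whole animals and 0.0329 ± 0.0570 in oocytes (-7.57 ± 0.49, and a fitted -13.17 without oocyte library 3, since the others had none), and myo-1 fell by 6.29 ± 0.60. For unc-54 the value was -2.33 ± 0.52 (adjusted p = 0.0303, -1.72 with library totals), with 41.4 ± 32.2 CPM in oocytes. Of the fits with 1 library left out, its call held only without oocyte library 1 (-3.18). It was lost without oocyte library 2 (-2.03) or 3 (-2.04) and without whole-animal library 1, 2 or 3 (-2.14, -2.37 and -2.45).

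Of 24 neuron markers 14 fell (18 adjusted over the list alone), with a median of -3.05, or -2.38 with library totals (adjusted p = 1.99e-09, and adjusted p = 0.0868 with an estimated correlation). The neuropeptide gene flp-14 fell by 4.55 ± 0.58 and egl-3, a neuropeptide convertase, by 3.93 ± 0.48. Of 13 sheath and spermatheca markers 5 fell (5 adjusted over the list alone), with a median of -1.04, or -0.35 with library totals (adjusted p = 0.0126, and adjusted p = 0.132 with an estimated correlation). Here emb-9 fell by 1.33 ± 0.19 (-0.66 with library totals) and the troponin gene tnt-4 by 4.93 ± 0.98. Hypodermis and cuticle (3 of 22 fell, 5 adjusted over the list alone, median -2.29, or -1.67 with library totals, adjusted p = 0.0598), coelomocyte and excretory markers (2 of 9 fell, 3 adjusted over the list alone, median -0.06, or 0.54 with library totals, adjusted p = 0.28) and sperm genes (2 of 7 fell, and 3 fell and 1 rose adjusted over the list alone, median -0.76, or -0.13 with library totals, adjusted p = 0.558) did not pass. The rule for named genes asks for a class symbol and at least 50 CPM in the higher group. By it the 8 largest falls were of the protease genes ctsa-1.2 (-4.45 ± 0.45, uncertain, overlapped on the opposite strand), cpr-9 (-3.98 ± 0.52), asp-1 (-3.72 ± 0.61) and asp-6 (-3.53 ± 0.44), the desaturase gene fat-2 (-3.70 ± 0.51), the lysozyme gene ilys-5 (-3.69 ± 0.28), the isocitrate lyase gene icl-1 (-3.67 ± 0.58) and vit-5 (-3.55 ± 0.48), with adjusted p from 4.65e-05 to 0.00893.

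In oocytes 10 lists of germline or housekeeping genes passed upward, each by a small amount and with few genes called. Camera sets a list against all other genes, of which 1272 fell and 72 rose here. A list without somatic genes can therefore test upward without a rise of its own messages. Medians were 0.23 for the proteasome, 0.17 for germ granules and for eggshell and egg activation, 0.16 for repressor targets and for P-body and decay proteins, 0.14 for RNA-binding regulators and for small RNA, 0.12 for the cell cycle, 0.11 for patterning and 0.10 for meiotic genes. In the same order the medians with library totals were 0.91, 0.84, 0.85, 0.84, 0.84, 0.82, 0.83, 0.80, 0.80 and 0.77. The camera adjusted p were, in that order, 5.45e-05, 0.000976, 0.000976, 0.000311, 0.0103, 0.00204, 0.000976, 0.000211, 0.00441 and 0.00295. With an estimated correlation the adjusted p were 0.132, 0.138, 0.0868, 0.138, 0.282, 0.206, 0.119, 0.119, 0.271 and 0.153. With the stricter filter 8 of the 10 were lost, all but the proteasome and the repressor targets, at adjusted p = 0.052 to 0.2, against lowest values over the alternatives of 8.55e-09 to 0.000109. The P-body list was also lost without oocyte library 2 (adjusted p = 0.0501, range 0.000109 to 0.175).

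Called members were 3 of 22 germ granule genes (3 adjusted over the list alone), 1 of 32 repressor targets (1), 2 of 50 cell cycle genes, 1 of 36 small RNA genes and 1 of 32 proteasome genes, the last 3 with none adjusted over the list alone. At an unadjusted p under 0.05 edgeR had 6 higher in the cell cycle list, 3 in the small RNA list and 10 in the proteasome list, and DESeq2 called 6, 3 and 5. In the other 5 lists edgeR called none, with 5 higher at an unadjusted p under 0.05 for RNA-binding regulators, patterning and meiotic genes each, 6 higher and 1 lower for eggshell genes, and 2 higher and 1 lower for P-body genes. DESeq2 called 5, 4, 2, 8 and 3 of these lists' members higher. The germ granule gene meg-1 rose by 0.46 ± 0.09 (adjusted p = 0.00538), with each library left out too, and meg-3 by 0.44 ± 0.10 (adjusted p = 0.0113), lost without whole-animal library 2 (0.38, adjusted p = 0.0608).

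The other rises of named genes were small, and leaving out single libraries ended them. They were tost-1 (0.61 ± 0.17), aly-2 (0.55 ± 0.16), cdc-25.2 (0.44 ± 0.13), ify-1 (0.44 ± 0.11), pbs-4 (0.39 ± 0.12, uncertain, overlapped on the opposite strand), gkow-1 (0.37 ± 0.11), tcc-1 (0.36 ± 0.10), acs-4 (0.34 ± 0.10), cyb-1 (0.33 ± 0.10) and spat-3 (0.31 ± 0.09), with adjusted p from 0.0188 to 0.0453. Each was lost without whole-animal library 1 and without whole-animal library 2. With whole-animal library 1 left out the values were, in that order, 0.49, 0.51, 0.46, 0.44, 0.36, 0.36, 0.34, 0.32, 0.34 and 0.35, and with library 2 left out 0.65, 0.59, 0.39, 0.44, 0.42, 0.36, 0.39, 0.38, 0.34 and 0.30. All but tost-1 were also lost without whole-animal library 3 (0.57, 0.49, 0.45, 0.39, 0.41, 0.35, 0.32, 0.31 and 0.30). Those of tost-1 (0.58), aly-2 (0.46), cdc-25.2 (0.40), ify-1 (0.39), pbs-4 (0.33), gkow-1 (0.34) and cyb-1 (0.29) were lost without oocyte library 1, and those of aly-2 (0.51), cdc-25.2 (0.38), pbs-4 (0.34), gkow-1 (0.32), tcc-1 (0.29), acs-4 (0.29) and spat-3 (0.30) without oocyte library 2. Without oocyte library 3 only spat-3 was lost (0.30). Of the preset germline genes, zif-1, nos-2, glp-1, lin-41, mex-3, oma-1, oma-2, puf-5, cgh-1, pgl-1, pgl-3, rme-2 and car-1 lay between 0.16 and 0.30 with adjusted p of 0.0834 or more, and oma-1 passed without oocyte library 2 (0.35, adjusted p = 0.0303).

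Apart from the proteasome, lists of the general machinery did not pass with TMM factors. Of 80 ribosomal protein genes 2 fell (2 adjusted over the list alone, median -0.17, or 0.49 with library totals, adjusted p = 0.186), rpl-11.2 among them (-1.84 ± 0.16, adjusted p = 2.09e-05, and -1.17 with library totals). Of 37 translation factors 2 fell (2 adjusted over the list alone, median 0.04, mean -0.03 and test upward, 0.72 with library totals, adjusted p = 0.196), with eef-1A.2 at -1.72 ± 0.21 (adjusted p = 0.000554, and -1.06 with library totals). Of 18 glycolysis genes 4 fell and 1 rose (4 and 1 adjusted over the list alone, median 0.02, mean -0.38 and test downward, 0.70 with library totals, adjusted p = 0.623), and gpd-2 (-1.70 ± 0.19, uncertain, overlapped on its own strand) and gpd-3 (-1.73 ± 0.25) were among those that fell (-1.02 and -1.07 with library totals). Of 37 respiratory genes 2 fell (2 adjusted over the list alone, median -0.09, or 0.59 with library totals, adjusted p = 0.864). Of 49 histone genes 1 fell, with none adjusted over the list alone (median 0.03, mean -0.04 and test upward, 0.72 with library totals, adjusted p = 0.238, with 4 lower at an unadjusted p under 0.05 and 2 by DESeq2). Of 12 mitochondrial mRNAs edgeR called none, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (median -0.36, or 0.31 with library totals, adjusted p = 0.558). Of 16 chaperone genes it called none, with 3 higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2 (median 0.21, or 0.88 with library totals, adjusted p = 0.0822).

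P-bodies against whole animals set the granules beside the animal extracts. Messages of RNA-binding regulators and repressor targets were higher in P-bodies. Relative to the typical gene, those of ribosomal proteins, mitochondria and several somatic tissues were lower. With an estimated correlation the regulators (camera adjusted p = 0.0446), the targets, ribosomal proteins and sheath markers (0.0409 each) passed. Mitochondrially encoded mRNAs (0.213), the nuclear-encoded respiratory chain (0.194), intestine (0.217), muscle (0.214) and vitellogenins (0.291) did not. Here spn-4 rose by 2.1 ± 0.11, from 211 ± 7.81 to 906 ± 55.1 CPM (adjusted p = 1.52e-08). The fall of vit-2 was 4.89 ± 0.43, from 4729 ± 713 to 159 ± 44.5 CPM (adjusted p = 5.91e-06). With library totals these were 5.29 and -1.70. List medians were then -0.06 for ribosomal proteins and 2.24 for the respiratory chain.

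Of 10162 genes 6790 changed, 2840 higher and 3950 lower, with 1695 at least 2-fold higher and 3009 at least 2-fold lower. With library totals 7781 were higher and 989 lower, and 1756 calls had the opposite sign. On log2(TPM + 1) the split was 7743 to 1322, on log2(TPM + 0.1) 7611 to 1156, with a mean TPM of at least 1 it was 6691 to 671 and without a filter 7974 to 1580. TMM factors from the 6 libraries compared gave 3787 to 3551, with a median shift of 0.24, and the stricter filter 1738 to 1641.

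Upward, 5 lists passed. Of 32 RNA-binding regulators 25 rose and 1 fell (25 and 1 adjusted over the list alone, median 0.93, or 4.12 with library totals, adjusted p = 8.26e-10, and adjusted p = 0.0446 with an estimated correlation). Of 32 repressor targets 24 rose and 4 fell (24 and 4, median 0.97, or 4.16, adjusted p = 5.52e-10, and adjusted p = 0.0409 with an estimated correlation). Calls in these lists included zif-1 (2.23 ± 0.09, uncertain, overlapped on the opposite strand), tra-2 (1.89 ± 0.10) and cpb-3 (1.74 ± 0.09), and rme-2 fell by 0.55 ± 0.11 (2.64 with library totals). Of 31 patterning genes 16 rose and 6 fell (16 and 6 adjusted over the list alone, median 0.63, or 3.82 with library totals, adjusted p = 0.000608, and adjusted p = 0.214 with an estimated correlation). Of 36 meiotic genes 21 rose and 4 fell (21 and 5 adjusted over the list alone, median 0.49, or 3.68 with library totals, adjusted p = 0.0002, and adjusted p = 0.167 with an estimated correlation), a call lost with the stricter filter (adjusted p = 0.0628, range 6.90e-10 to 0.0628). Of 36 small RNA genes 20 rose and 10 fell (20 and 10 adjusted over the list alone, median 0.44, or 3.63 with library totals), and the list's adjusted p of 0.0485 rose above the threshold under 8 alternatives (range 1.20e-06 to 0.562, and adjusted p = 0.248 with an estimated correlation).

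Ribosomal protein genes fell in 79 of 80 cases (79 adjusted over the list alone), with a median of -3.25, or -0.06 with library totals (adjusted p = 5.06e-64, and adjusted p = 0.0409 with an estimated correlation). The fall was 3.98 ± 0.13 for rps-13 and 3.23 ± 0.11 for rpl-34 (-0.79 and -0.04 with library totals). All 12 mitochondrial mRNAs fell (12 adjusted over the list alone, median -5.96, or -2.77 with library totals, adjusted p = 3.83e-09, and adjusted p = 0.213 with an estimated correlation), and ctc-3 fell by 6.07 ± 0.26. Of 37 translation factors 24 fell and 2 rose (median -0.88, or 2.31 with library totals, adjusted p = 0.0002, and adjusted p = 0.194 with an estimated correlation). Of 37 respiratory genes 30 fell and 1 rose (-0.95, or 2.24, adjusted p = 1.07e-05, and adjusted p = 0.194 with an estimated correlation). Of 32 proteasome genes 26 fell (-0.78, or 2.41, adjusted p = 0.000103, and adjusted p = 0.167 with an estimated correlation). Of 18 glycolysis genes 15 fell (-1.66, or 1.53, adjusted p = 5.04e-06, and adjusted p = 0.0409 with an estimated correlation). These 4 lists had the same counts adjusted over the list alone. Of 16 chaperone genes 11 fell and 1 rose (11 and 2 adjusted over the list alone, -1.03, or 2.16, adjusted p = 0.0254, and adjusted p = 0.436 with an estimated correlation). Of 49 histone genes 32 fell and 6 rose (33 and 6 adjusted over the list alone, -1.84, or 1.34, adjusted p = 0.000629, and adjusted p = 0.395 with an estimated correlation).

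With library totals the calls of translation factors (adjusted p = 0.142, range 2.51e-06 to 0.142), respiratory genes (0.708, range 1.45e-06 to 0.708), glycolysis (0.745, range 4.32e-07 to 0.745) and chaperones (0.899, range 0.00292 to 0.899) were lost, chaperones also with DESeq2, and the sign of the proteasome list's test turned (0.0158, range 2.06e-06 to 0.0158). That scaling raised the median gene by 3.19, and the median of the proteasome list (2.41) stayed below this. The histone list was lost with length offsets (range 2.36e-05 to 0.165).

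Vitellogenins and the markers of intestine, muscle and sheath were lower in P-bodies than in whole animals with both scalings. All 6 vitellogenins fell (6 adjusted over the list alone, median -4.82, or -1.63 with library totals, adjusted p = 0.000629, and adjusted p = 0.291 with an estimated correlation). Of 33 intestine markers 31 fell (31 adjusted over the list alone, -4.93, or -1.74, adjusted p = 7.34e-09, and adjusted p = 0.217 with an estimated correlation). Of 29 muscle markers 25 fell and 1 rose (25 and 1 adjusted over the list alone, -4.82, or -1.63, adjusted p = 2.5e-09, and adjusted p = 0.214 with an estimated correlation), with myo-2 at 0.0350 ± 0.00589 CPM in P-bodies and 9.88 ± 1.38 in whole animals. Of 13 sheath markers 12 fell (12 adjusted over the list alone, -4.20, or -1.01, adjusted p = 5e-05, and adjusted p = 0.0409 with an estimated correlation). Lists that did not pass were neurons (15 of 24 fell and 3 rose, -3.23, or -0.04, adjusted p = 0.0685), hypodermis (16 of 22 fell and 3 rose, 17 and 3 adjusted over the list alone, -4.08, or -0.91, adjusted p = 0.368), coelomocytes (4 of 9 fell and 3 rose, -0.12, mean -0.60 and test upward, or 3.07, adjusted p = 0.61), sperm (3 of 7 fell, -0.80, or 2.36, adjusted p = 0.863), germ granules (8 of 22 fell and 4 rose, -0.10, or 3.09, adjusted p = 0.863), P-body and decay proteins (9 of 23 rose and 5 fell, 0.02, or 3.21, adjusted p = 0.0778), eggshell (10 of 23 fell and 7 rose, -0.20, mean -0.25 and test upward, or 2.99, adjusted p = 0.642) and cell cycle (28 of 50 fell and 10 rose, -0.37, or 2.82, adjusted p = 0.387). Apart from hypodermis, these had the same counts adjusted over the list alone.

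Single genes were again ranked among those with a class symbol and at least 50 CPM in the higher group. By that rule the 8 largest rises were of mbk-1 (2.34 ± 0.13), the histone demethylase gene rbr-2 (2.34 ± 0.12, uncertain, overlapped on the opposite strand), mbk-2 (2.32 ± 0.10), mfsd-13.1 (2.3 ± 0.16, uncertain, overlapped on its own strand), mom-4 (2.3 ± 0.19), the receptor kinase gene cam-1 (2.26 ± 0.14), gap-2 (2.25 ± 0.10, uncertain, overlapped on the opposite strand) and the cyclophilin gene cyn-8 (2.25 ± 0.17). By the same rule the 8 largest falls were all of mitochondrial mRNAs, ctc-3, atp-6, ctc-2, ctc-1, ctb-1, nduo-5, nduo-1 and nduo-4, at -6.07 to -5.77, of which atp-6, nduo-5 and nduo-1 are uncertain because a gene on the same strand overlaps each. On log2(TPM + 1) the call of nduo-4 was lost (-3.76). The granule genes dcap-2 (2.14 ± 0.11, uncertain, overlapped on the opposite strand) and meg-1 (1.01 ± 0.09) rose and pab-1 fell by 1.87 ± 0.12 (1.32 with library totals). The tagged car-1 had -0.41 ± 0.16 (adjusted p = 0.0372, 2.78 with library totals), kept without P-body library 2 (-0.52). The call was lost without P-body library 1 (-0.39) or 3 (-0.31) and without whole-animal library 1, 2 or 3 (-0.33, -0.42 and -0.42), with RLE factors (-0.36), DESeq2 (-0.36), no filter (-0.16) and TMM factors from the 6 libraries compared (-0.16). For pgl-3 the value was -0.45 ± 0.14 (adjusted p = 0.0115, 2.74 with library totals), lost without whole-animal library 1 (-0.38) or P-body library 3 (-0.34), without a filter (-0.20) and with TMM factors from the 6 libraries compared (-0.21). For puf-5 it was 0.33 ± 0.11 (adjusted p = 0.0186), lost without whole-animal library 2 (0.30) or 3 (0.32) or P-body library 2 (0.30), with the stricter filter (0.16), thinned totals (0.24) and length offsets (0.21). For cgh-1 it was 0.35 ± 0.12 (adjusted p = 0.0176), lost without whole-animal library 3 (0.34), with the stricter filter (0.18), thinned totals (0.27) and length offsets (0.20). For pgl-1 it was 0.29 ± 0.13 (adjusted p = 0.0682), and it passed with RLE factors (0.34), DESeq2 (0.34), voom (0.28), no filter (0.54) and TMM factors from the 6 libraries compared (0.53).

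**Figure D3:**
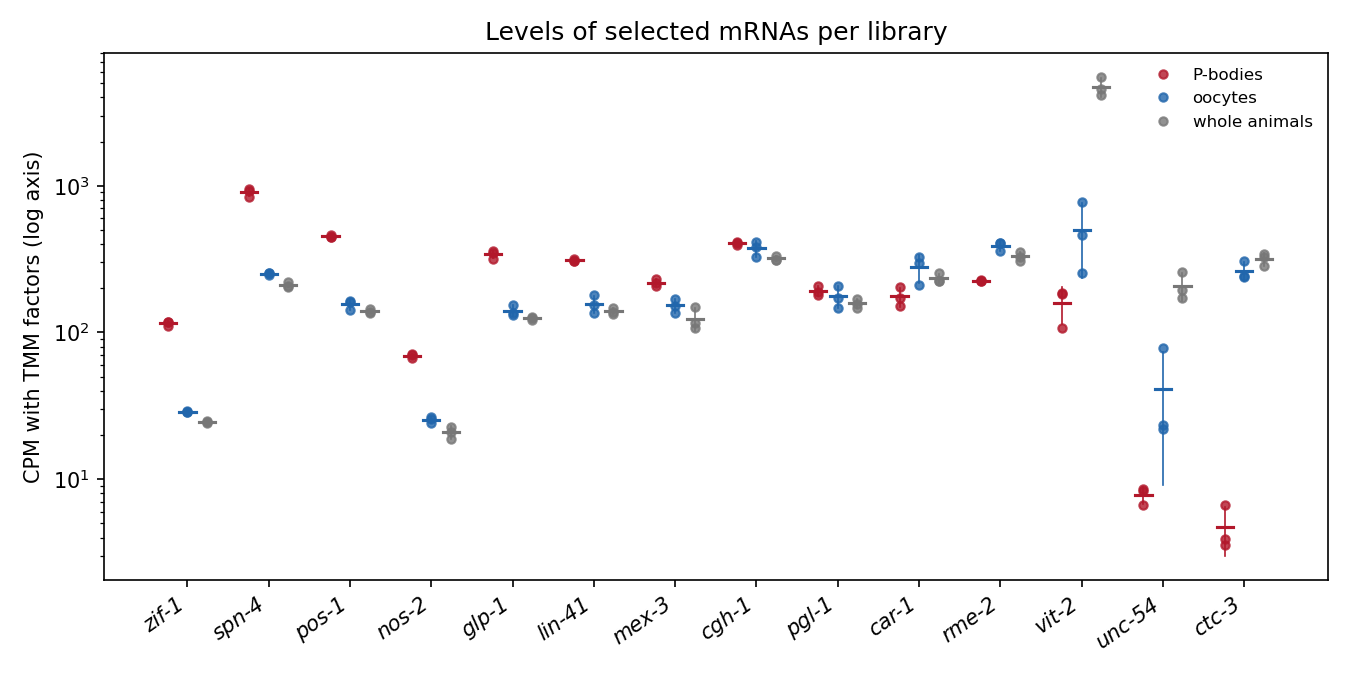
Points give the CPM (TMM-scaled, log axis) of 14 genes in 3 libraries each of P-bodies, oocytes and whole animals, with the group mean as a line and its SD as a bar. The 3 P-body points of spn-4 average 906 CPM against 251 in oocytes and 211 in whole animals, and those of ctc-3 average 4.71 against 263 and 316. With library totals in place of TMM the falls of car-1, rme-2 and vit-2 from oocytes to P-bodies turn into rises, the call of unc-54 is lost with its value above 0, and ctc-3 still falls.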

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

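Length offsets and thinned protein-coding counts were chosen after seeing the data. Of the values of named genes under the alternatives, 4147 kept their direction and their side of the threshold, 171 fell short of it, 117 newly passed it and 216 changed sign. Of the list tests 873 kept both, 30 fell short and 6 changed sign, and of the counts and shares 124 stayed within their tolerance and 48 moved. The changes of sign of named genes and lists all arose with library totals or TPM. Without TMM factors library totals raised the median gene by 2.51 for P-bodies against oocytes and by 3.19 for P-bodies against whole animals, and TPM values raised it by 2.19 to 2.32 and by 2.78 to 2.92. For oocytes against whole animals library totals raised it by 0.68 and TPM values by 0.55 to 0.60. Other median shifts over 0.1 were 0.22 and 0.25 without a filter for P-bodies against oocytes and against whole animals, and for P-bodies against whole animals 0.24 in the fit of 6 libraries and -0.17 with the stricter filter. They were -0.10 and -0.13 with length offsets for these comparisons, and -0.13 with length offsets and the replicate block for P-bodies against whole animals. Protein-coding depth was lowest in oocytes and whole animals. At an equal protein-coding depth 9486 to 9873 genes were seen in P-body, 9578 to 10257 in oocyte and 11944 to 12038 in whole-animal libraries. Offsets on GC content, with and without a block, were not run.

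The stricter filter, which tested 4134 genes, called 3376 genes for P-bodies against oocytes, 202 for oocytes against whole animals and 3379 for P-bodies against whole animals, against 5640, 1344 and 6790 as reported. It called 8 lists for oocytes against whole animals against 15. A test against a 1.5-fold change called 3513 genes for P-bodies against oocytes, by construction fewer. For oocytes against whole animals library totals called 6481 genes, log2(TPM + 1) 5606, log2(TPM + 0.1) 5706, a mean TPM of at least 1 4914 and TPM without a filter 4275. All of these leave out the TMM factors by construction, and other causes were not tested. Camera with an estimated correlation called 4, 0 and 5 lists of 25, against 16, 15 and 17 at the preset correlation. For the count of 0, camera had 8 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.0868, and camera at the preset correlation on DESeq2 statistics called 16. Fry, which asks whether a list's genes move one way, called 22, 16 and 22.

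With 1 library left out, 4746 to 5804 genes and 15 to 17 lists were called for P-bodies against oocytes, 888 to 1535 genes and 14 to 18 lists for oocytes against whole animals, and 6315 to 6521 genes and 17 to 17 lists for P-bodies against whole animals. The count of 888, against 1344 as reported, came without whole-animal library 2. Genes called were 4745, 1287 and 5714 with thinned protein-coding counts and 5628, 1434 and 6824 with length offsets.

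The groups share replicate numbers, but the labels do not say that a number marks a shared batch. Deviations from the group means correlated between same-numbered oocyte and P-body libraries at 0.137, 0.0997 and 0.104, between whole-animal and P-body libraries at -0.00643, -0.0415 and 0.142, and between oocyte and whole-animal libraries at -0.113, -0.0959 and 0.0900, so the numbers were not taken to pair the samples. Every oocyte and P-body library correlated best with its own number in the other group, which is a hint from the data and not the design. With the replicate block 5354, 1221 and 6650 genes and 16, 16 and 16 lists were called, and with length offsets and the replicate block 5366, 1323 and 6677 genes.

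With library totals, which raise all genes alike, the tests of 3 lists changed sign for P-bodies against oocytes, cell cycle, spindle and centrosome (adjusted p = 0.000551), translation factors (0.684) and the proteasome (0.603). For P-bodies against whole animals those of translation factors (0.142), the respiratory chain and ATP synthase (0.708) and the proteasome (0.0158) did. Relative to the typical gene these lists did not turn, since their medians of 2.08, 1.69 and 1.53 stayed below the shift of 2.51, and those of 2.31, 2.24 and 2.41 below the shift of 3.19. Over the 19 alternatives at the preset correlation the adjusted p of these lists ran, in the same order, from 0.000551 to 0.0333, 2.61e-09 to 0.684 and 2.04e-14 to 0.603, and from 2.51e-06 to 0.142, 1.45e-06 to 0.708 and 2.06e-06 to 0.0158. Under the same common shift lists that had not passed did so, which is not read as a change relative to other genes. For P-bodies against oocytes these were P-body and decay proteins, germ granules, eggshell, the small RNA pathway and hypodermis. For oocytes against whole animals they were translation factors, chaperones and hypodermis. For P-bodies against whole animals they were P-body and decay proteins, germ granules, eggshell, cell cycle, neurons and hypodermis. The genes that follow had fallen and had values above 0 with library totals, given first, and with TPM, given in brackets where the sign changed there too. For P-bodies against oocytes these log2 values were as follows. rnp-8 lay at 1.97 (1.80 and 1.82), cul-4 at 1.47 (1.23 and 1.28), gpr-2 at 0.67 (0.46 and 0.49) and plk-2 at 1.69 (1.48 and 1.52). bub-1 lay at 0.35 (0.18), mat-2 at 0.71 (0.51 and 0.54), iff-1 at 0.36 (0.26) and eif-3.I at 0.78 (0.60 and 0.61). cyc-2.1 lay at 0.18 (0.0608 and 0.0623), pbs-7 at 0.93 (0.74 and 0.76), rpn-1 at 1.06 (0.86 and 0.87) and enol-1 at 0.51 (0.34). gpd-4 lay at 0.20 (0.0338 and 0.0354), his-48 at 0.51 (0.37), his-63 at 0.0789 and ifc-2 at 0.47 (0.11 and 0.27). pgl-3 lay at 1.79 (1.61 and 1.63), rme-2 at 1.71 (1.53 and 1.54), unc-54 at 0.19 (0.17 and 0.20) and vit-2 at 0.92 (0.79 and 0.80). vit-6 lay at 1.15 (1.04 and 1.05), car-1 at 1.85 (1.69), pab-1 at 0.99 (0.81) and csr-1 at 0.38 (0.11). For P-bodies against whole animals they were as follows. rnp-8 lay at 2.70 (2.45 and 2.49), cul-4 at 2.09 (1.73 and 1.83), gpr-2 at 1.43 (1.09 and 1.19) and plk-2 at 2.44 (2.12 and 2.19). csr-1 lay at 1.1 (0.78 and 0.81), iff-1 at 1.07 (0.85), eef-1B.1 at 1.32 (1.08 and 1.09) and ucr-2.3 at 0.80 (0.53 and 0.57). asb-2 lay at 0.67 (0.42 and 0.44), pbs-7 at 1.72 (1.46 and 1.48), rpn-1 at 1.87 (1.59 and 1.63) and enol-1 at 1.3 (1.02 and 1.03). pfk-1.1 lay at 1.26 (0.99 and 1.11), hsp-1 at 0.87 (0.62 and 0.63), his-48 at 1.15 (0.92) and his-63 at 0.61 (0.37). pgl-3 lay at 2.74 (2.49 and 2.52), rme-2 at 2.64 (2.39 and 2.40), car-1 at 2.78 (2.52 and 2.53) and pab-1 at 1.32 (1.06 and 1.07).

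As shares of TPM, ribosomal RNA genes took 26.8% in P-bodies, 80.4% in oocytes and 84.9% in whole animals. Protein-coding genes took 99.2%, 91.9% and 88.9% with ribosomal RNA left out and 71.6%, 14.9% and 10.1% of TPM. Ribosomal protein genes took 0.604%, 4.38% and 4.31%, or 1.28%, 1.84% and 1.32% of TPM, and mitochondrially encoded mRNAs 0.0105%, 0.495% and 0.575%, or 0.0143%, 0.139% and 0.120%. Vitellogenin genes took 0.332%, 0.873% and 8.23%, or 0.0886%, 0.0445% and 0.329%, and histone genes 0.578%, 1.07% and 0.893%, or 1.15%, 0.554% and 0.333%. Leaving out ribosomal RNA raises the shares by construction, and for TPM the cause was not tested. The P-body fold change had rho -0.217 with mean oocyte CPM with the stricter filter, against -0.0201. That filter keeps genes low in oocytes if high in P-bodies, which can lower rho by construction.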

Other observations

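Small noncoding RNAs, cell death genes and nuclear pore genes below were tested and picked after their values were seen, and so were the median levels per oocyte library. Small nucleolar RNAs, which guide the modification of ribosomal RNA, were low in P-bodies. Of 125 tested against oocytes 121 fell and 1 rose, K10D3.10 (1.23 ± 0.28, adjusted p = 0.00253), and with library totals 116 fell and 3 rose. Their summed level was 45.6, 17.4 and 35 CPM in the P-body libraries, 1699, 267 and 803 in the oocyte libraries and 381, 889 and 972 in the whole-animal libraries. Many lie inside introns of other genes and are uncertain one by one. All 26 tested transfer RNA genes fell, also with library totals, and 17 of them had no count in any P-body library (edgeR, 0 higher, also at an unadjusted p under 0.05 and by DESeq2, which called 21 lower). Their summed level was 0.0186, 0.00668 and 0.0227 CPM in the P-body libraries and 79.7, 1.49 and 3.10 in the oocyte libraries, so oocyte library 1 carried most of it. Fits with 1 library left out filtered the genes anew, so the number tested can differ. In them 21 (without oocyte library 1) to 39 transfer RNA genes fell. Of 28 spliceosomal small nuclear RNAs 22 fell and 0 rose (0 at an unadjusted p under 0.05, 0 by DESeq2), but only 3 fell with library totals. Without oocyte library 1 14 fell, again among genes filtered anew.

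Among 88 classes of gene symbols tested, the ced class, named for abnormal cell death, was higher in P-bodies than in oocytes. Of 12 tested members 10 rose and 1 fell, with a median log2 fold change of 0.97, or 3.47 with library totals (camera adjusted p = 0.00421, and adjusted p = 0.310 with an estimated correlation). The engulfment gene ced-7, which overlaps a gene on the other strand and is uncertain, rose by 1.70 ± 0.10 from 86.1 ± 4.10 to 280 ± 11.5 CPM (SD, n = 3, edgeR adjusted p = 3.6e-08), and the engulfment gene ced-5 rose by 1.53 ± 0.11 (1.47e-07). The caspase gene ced-3 rose by 1.14 ± 0.10 (1.3e-06). With library totals these 3 lay at 4.21, 4.05 and 3.66. The value of ced-12 was -0.42 ± 0.13 (adjusted p = 0.0128), or 2.08 with library totals, and its call was lost without oocyte library 3 (-0.27, adjusted p = 0.0866) and without P-body library 2 (-0.36, 0.0560), in a range of 0.0107 to 0.0866 over the libraries left out. Nuclear pore genes of the npp class were lower, with 16 of 26 fallen and 1 risen, npp-8 (0.91 ± 0.14), which overlaps a gene on the other strand and is uncertain. Their median was -0.73, which turned to 1.77 with library totals (camera adjusted p = 0.00111, and adjusted p = 0.722 with an estimated correlation).

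Messages for ribosomal proteins were lower in P-bodies than in oocytes, with a median of -3.05 over 80 genes, but -0.53 with library totals, where they took 0.402% of all counts in P-bodies against 0.525% in oocytes. Loss of short transcripts is argued against, since 95% of the medians of 10000 lists matched on transcript length lay between -0.34 and 0.50. Loss of abundant transcripts is argued against likewise, with -0.54 to 0.11 for lists matched on oocyte CPM. A hypothesis is that P-bodies may hold fewer of these messages relative to other messages, but this difference between granule and cell was not tested apart from the sort. Losses in sorting, and the debris step left out for P-bodies, stay open because they follow the groups, and so does depth, since thinning keeps the expected ratios and the median of -3.12 at an equal protein-coding depth does not test it.

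Somatic marker genes of 5 lists had a median of -1.36 over 114 genes in P-bodies against oocytes, though neuron markers lay at 0.29, and with library totals the medians lay above 0 (intestine 0.90, vitellogenins 1.18, muscle 0.09, neurons 2.81 and hypodermis 1.24). Loss of abundant transcripts is argued against, since 95% of medians of lists matched on oocyte CPM lay between -0.25 and 0.36. Somatic RNA carried over with dissected oocytes may add to it: by summed CPM 4 of the 5 lists were highest in oocyte library 1, such as intestine markers at 165 CPM against 37.1 and 101, vitellogenins at 2530 against 733 and 1585 and muscle markers at 517 against 261 and 224. Summed neuron markers were highest in oocyte library 2 (97.6 against 87.3 and 89.4). Most of that sum was 1 gene, maco-1, at 70.3 CPM in library 2, 58.1 in library 1 and 62.4 in library 3. By median log2 CPM neuron markers were highest in library 1 (-1.47 against -3.09 and -2.28), as were the other 4 lists, which is what carryover predicts. Carryover stays open, since the planned measure was the summed level and the medians were looked at afterwards. A difference between P-bodies and oocytes themselves stays open, untested.

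Fewer genes were higher than lower in oocytes against whole animals, 72 against 1272, a ratio of 0.0566. With library totals it was 4.39 and with RLE factors 0.124, but library totals raise all genes by a median of 0.68, so the ratio moves by construction and does not test the scaling as a cause: higher genes went from 72 to 5278 and lower genes only from 1272 to 1203. Whether a single divergent oocyte library adds to it stays open, since the highest ratio with 1 oocyte library left out was 0.213 (without library 3, 227 against 1064), between the bounds set for either answer. Without whole-animal library 1, 2 or 3 the higher genes were 28, 23 and 32. Among the falls were 26 of 33 intestine, 19 of 29 muscle and 14 of 24 neuron markers and all 6 vitellogenins, but only 3 of 22 hypodermis markers. The medians of these lists were below 0 with library totals too, though none passed with an estimated correlation. RNA make-up thus differed between oocytes and whole animals in somatic genes, but how much of the imbalance this accounts for was not tested.

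Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05, and 1 split, the real one, gave as many genes as reported. It gave 5640, 1344 and 6790 genes by edgeR, and the highest other split gave 0 in each comparison. At an unadjusted p under 0.05 the highest other split gave 796, 838 and 43, and by DESeq2 284, 134 and 0. Each of the other splits mixed libraries of both groups, so the difference between the groups entered its spread. Few calls there follow by construction and do not speak against chance.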
